A study of Homo sapiens with 6 samples.

How the data were processed

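The series holds RNA sequencing of human skeletal muscle myoblasts in 3 groups of 2 libraries, collected at day 0, day 3 and day 6 in differentiation medium. Total RNA was made into stranded, paired-end libraries, per the labels' protocols, and the medium held horse serum and dexamethasone from the start of differentiation. Reads were processed with cutadapt 1.14, STAR and featureCounts and compared with DESeq2 on hg38, per the submitters' processing notes. The gene annotation, the way multi-mapping reads and strand were treated, and the size factors are not given in the sources used here.

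The values used here are those of 2 comparison tables made by the authors, day 3 against day 0 and day 6 against day 0. Per the file headers, each table holds a mean signal in scaled counts over the libraries compared, a log2 fold change, its SE, a Wald score, a p-value and an adjusted p-value. The log2 fold changes and their SEs are those deposited by the authors, and the deposited Wald score was checked to be their ratio in each line. Whether the fold changes had been shrunken is not given in the sources used here. They were treated as unshrunken, since genes without reads at day 0 kept very large values, such as 15.19 ± 4.00 for UNC45B at day 6. The deposited p-value is that of the authors' DESeq2 Wald test, and the deposited adjusted p-value is its Benjamini-Hochberg correction after that tool's filter on low counts. The deposited signal was treated as the mean of the 4 libraries of a comparison, and day 0 levels implied by the 2 tables differed by a median log2 of 0.0232 over 10613 genes. Values per library were not analysed here. No model was therefore refitted, no library was left out, and the depth of single libraries is not stated.

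Of the 20137 gene symbols in each table, 19954 were found in GENCODE 29, 19522 of them protein coding. The lines of Y-linked genes were left out because the donor is a person, which left 20093. Reads were present for 16719 genes in the day 3 table and 16882 in the day 6 table, and 15121 and 14938 had an adjusted p. Coordinates are those of GENCODE 29 on GRCh38, counted from 1.

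A gene was called changed at a deposited adjusted p under 0.05. The level of each group was implied from the mean and the fold change with equal group sizes. A group implied under 0.25 scaled counts per library was taken as without reads, and the fold change was then given only as a bound against 3 scaled counts over 2 libraries (1.5 per library). Since the size factors are not known, the number of reads at that level is not known either, and these bounds are approximate. Implied totals per library were 16022119 at day 0 and 21787580 at day 3 by the first table, and 16310139 and 23072539 at day 6 by the second. The log2 fold changes of genes with a mean of 10000 or more had a median SE of 0.07 at day 3 and 0.21 at day 6. A call needed a change well above 1 SE, so that changes somewhat larger than these sizes were also missed in abundant genes. At day 6, COL6A2, with a mean of 18520, had 0.43 ± 0.22 and was not called (DESeq2 Wald test, adjusted p = 0.120). For the centred scaling the median log2 fold change of genes with a mean of 100 or more was subtracted, the Wald p-values were computed again and were adjusted over the genes with a deposited adjusted p.

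Day 6 and day 3 were compared for each gene by the difference of their log2 fold changes over the root of the summed squared SEs, with a two-sided normal p and Benjamini-Hochberg adjustment. The covariance from the shared day 0 libraries was left out, which widens the variance. The correlation of both sets of fold changes was set beside 100 simulated draws of unchanged groups that shared their day 0 libraries. For the overlap of calls, as many genes as had been called were taken from each end of such draws, a comparison added after the data were seen.

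A total of 33 gene lists was fixed before any value was seen. Each was tested with cameraPR of limma 3.58.1 (R 4.3.3) on the Wald scores with a preset inter-gene correlation of 0.01, and p-values were adjusted over all lists and both comparisons. For each list the members called over all genes were counted, and again with p-values adjusted over the list alone. In 2 lists, 1 member each was not analysed here. In the list of mRNAs encoded in mtDNA, 2 lines each merge a pair of overlapping genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

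Genes were named by a rule fixed before any value was seen. In each comparison it takes the 6 highest and 6 lowest log2 fold changes among called genes with a mean of 100 or more, and from each list the 3 measured members with the smallest adjusted p, or fewer where a list has 1 sentence. It adds 20 genes named whatever their values, and for day 6 against day 3 the 6 highest and 6 lowest differences among called genes with a mean of 100 or more in both tables. The gene said to lead a list had its smallest adjusted p. Exceptions are said to have been chosen after their values were seen.

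The steps were tested on simulated data in which 100 genes were changed at each fold size among 14746. The changed genes were drawn from those with a mean of 100 or more in both comparisons, so the shares found do not cover scarcer genes. At a log2 change of 1, the centred test found 90% of them for day 3 and 63% for day 6, and the difference test found 45%. At a log2 change of 2 it found 99% and 98%, and the difference test 94%. Among unchanged genes 0.0825%, 0.0413% and 0% were called. Noise was drawn from the deposited SEs and tested against the same SEs. These shares therefore cannot show whether SEs from 2 libraries per group were right. Of the lists, 1 of 1 moved and 0 of 32 unmoved were called. Scores for the list test were drawn independently for each gene, so correlated lists were not tried.

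Alternatives fixed in advance were adjusted p under 0.01 and 0.1, a 2-fold minimum, genes with a mean of at least 10 or 100, adjustment over every gene with a p-value, the centred scaling, preset correlations of 0.05 and 0.1, ranks or log2 fold changes in place of Wald scores, and a covariance for the shared day 0 libraries. Those added after seeing the data were list tests on centred Wald scores, the centred scaling with a 2-fold minimum, and the centred scaling of genes named after their values were seen.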

Results

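RNA sequencing was used to follow gene expression as cultured human muscle precursor cells differentiated. The cells, human skeletal muscle myoblasts (HSMM), are proliferating mononucleated cells that leave the cell cycle and fuse into multinucleated myotubes when growth factors are withdrawn. They were moved from growth medium to a low-serum medium that also held dexamethasone, a synthetic glucocorticoid, and were collected at day 0, day 3 and day 6. Each of the 3 groups held 2 libraries of total RNA. The series title sets these libraries beside work on the packaging of mitochondrial DNA (mtDNA), so that genes of mtDNA maintenance were among those named in advance. Dexamethasone and the change of serum began together, and these libraries cannot separate their effects.

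Values were read from the authors' deposited table for day 3 against day 0 and the one for day 6 against day 0. Each gives a gene's mean scaled count over the 4 libraries compared, its log2 fold change over day 0 and the standard error (SE) of that change. The scaled counts summed to 18904849 per library in the day 3 table and to 19691339 in the day 6 table. Counts per library were not analysed here, so neither the depth of single libraries nor the number of libraries that shared a direction can be given. For genes with a mean of 100 or more, the median SE was 0.15 at day 3 and 0.26 at day 6, so the day 6 comparison resolved smaller changes less well. Nothing in the labels says that the libraries of a group came from separate cultures, and the p-values then measure only the spread between these libraries, which may be technical.

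Most genes moved upward together in the deposited scaling. The median log2 fold change of genes with a mean of 100 or more was 0.53 at day 3 (10820 genes) and 0.34 at day 6 (10818 genes). Counts of called genes are therefore given as deposited and again after these medians were subtracted from every fold change and the Wald tests recomputed, which is called the centred scaling.

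**Figure D1:**
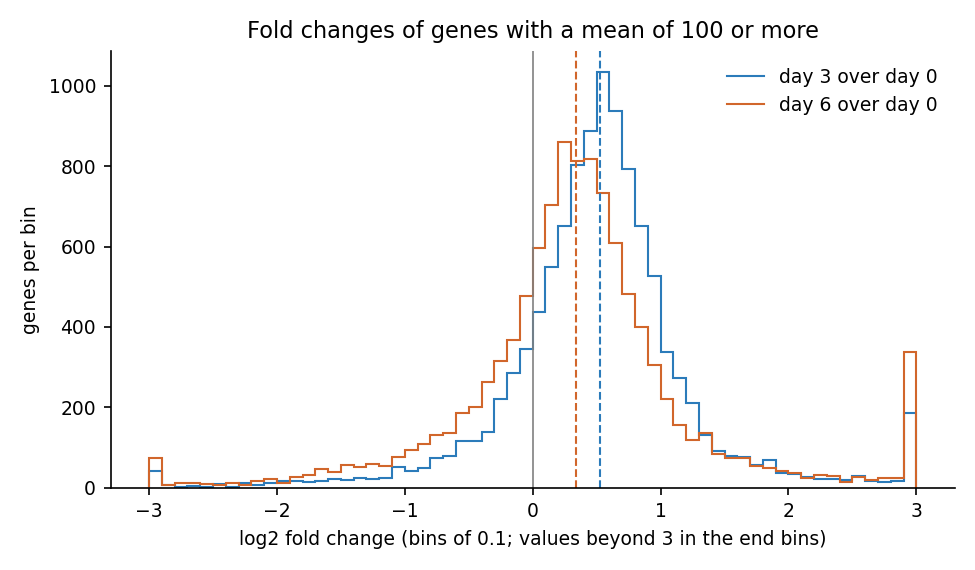
Number of genes (vertical axis) per bin of log2 fold change (horizontal axis) for genes with a mean of 100 or more, day 3 over day 0 in blue and day 6 over day 0 in orange. The dashed lines mark the medians, 0.53 at day 3 and 0.34 at day 6, both to the right of the grey line at 0, and the end bins hold all values beyond 3 in size.

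After 3 days in differentiation medium, genes of the contractile apparatus and of its control had risen steeply. In the authors' deposited table for day 3, MYOG, the transcription factor that opens terminal muscle differentiation (chr1:203083132-203086036, minus strand, GRCh38), had a log2 fold change of 6.87 ± 0.36 (SE, 2 libraries per group, adjusted p = 3.89e-78). The same authors' deposited table gave 5.93 ± 0.18 for MYH3, the embryonic myosin heavy chain (chr17:10628526-10657309, minus strand), and 8.71 ± 1.31 for CKM, the muscle creatine kinase, which had under 1 scaled count per library at day 0. MYOD1, the myoblast determination factor (chr11:17719568-17722131, plus strand), rose by 1.21 ± 0.10 in the authors' deposited table, whereas MYF5, a factor of undifferentiated myoblasts (chr12:80716912-80719673, plus strand), fell by 1.03 ± 0.15. PAX7, a marker of muscle stem cells, was scarce, with an implied level of 4.04 scaled counts per library at day 0, and rose to 44.5 (log2 fold change 3.46 ± 0.86 in the authors' deposited table).

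Of the 52 measured sarcomere genes, 37 rose, 1 fell and 14 did not pass the test as deposited, with 40 higher and 1 lower adjusted over the list alone. Centring gave 32 higher and 3 lower. Their median log2 fold change was 4.54, or 3.76 with the 8 members that had a group without reads at their lower bound. The 3 members with the smallest adjusted p were TTN, the giant elastic protein titin, NEB, the thin-filament ruler nebulin, and TNNT2, a troponin of heart and developing muscle. In the authors' deposited table they rose by 5.72 ± 0.07, 4.57 ± 0.10 and 5.74 ± 0.10. The list stood above other genes (limma cameraPR on the Wald statistics, adjusted p = 8.01e-22).

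Among 25 measured genes of excitation-contraction coupling and calcium handling, 17 rose, 0 fell and 8 did not pass the test, with 17 higher and 0 lower adjusted over the list alone and 10 higher and 2 lower when centred (cameraPR adjusted p = 3.13e-06). RYR1, the calcium release channel of the sarcoplasmic reticulum (chr19:38433699-38587564, plus strand), rose by 7.68 ± 0.15, STAC3, which couples that channel to the voltage sensor, by 3.59 ± 0.12, and BIN1, a membrane-bending protein of the T-tubules, by 2.60 ± 0.09 in the authors' deposited table. Of 12 genes of the acetylcholine receptor and postsynapse, 9 rose, 1 fell and 2 did not pass the test, with 9 higher and 1 lower adjusted over the list alone. When centred, the counts were 9 higher and 1 lower (cameraPR adjusted p = 7.88e-09). MUSK, the kinase that organises the postsynaptic membrane, and CHRNG, the fetal receptor subunit, rose by 3.01 ± 0.08 and 5.30 ± 0.25 in the authors' deposited table. Myogenic regulators (13 measured) gave 11 that rose and 1 that fell, the same numbers adjusted over the list alone, and 8 higher and 1 lower when centred (cameraPR adjusted p = 0.0138). After MYOG and MYOD1 the third member was SIX4, a homeobox factor of muscle precursors, at 1.70 ± 0.12 in the authors' deposited table. Myoblast fusion genes (13 measured) gave 9 that rose and 2 that fell, again the same adjusted over the list alone, and 6 higher and 2 lower when centred (cameraPR adjusted p = 0.00171). Besides STAC3, ITGA7, a laminin receptor subunit, and CDH15, the muscle cadherin, rose by 1.31 ± 0.07 and 1.60 ± 0.09 in the authors' deposited table. Among 20 muscle metabolism enzymes and carriers, 13 rose, 1 fell and 6 did not pass the test, with 14 higher and 1 lower adjusted over the list alone. Centring gave 12 higher and 2 lower, and the list as a whole did not pass (cameraPR adjusted p = 0.153). PHKA1, a phosphorylase kinase subunit, rose by 2.59 ± 0.14 in the authors' deposited table, while LDHA, the lactate dehydrogenase chain of glycolytic tissues, fell by 1.53 ± 0.08.

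Glucocorticoid-induced genes rose as well. FKBP5, a co-chaperone of the glucocorticoid receptor (chr6:35573585-35728583, minus strand), and TSC22D3, the leucine zipper protein GILZ, had log2 fold changes of 5.21 ± 0.10 and 6.48 ± 0.12 in the authors' deposited table. FOXO3, a transcription factor of atrophy programmes, rose by 3.11 ± 0.11 in the authors' deposited table. Of the 23 measured members of the list, 19 rose, 3 fell and 1 did not pass the test, with 19 higher and 3 lower adjusted over the list alone. When centred, the counts were 17 higher and 3 lower (median log2 fold change 2.84, cameraPR adjusted p = 2.78e-17).

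Cholesterol synthesis moved nearly as a block, with 22 of 23 measured genes higher and 0 lower as deposited. The counts were unchanged adjusted over the list alone and when centred, and the median log2 fold change was 3.11 (cameraPR adjusted p = 9.06e-65). HMGCS1, the synthase at the start of the mevalonate pathway (chr5:43289395-43313512, minus strand), rose by 4.10 ± 0.11, SREBF2, the transcription factor of the pathway, by 3.31 ± 0.09 and FDFT1, squalene synthase, by 3.30 ± 0.10 in the authors' deposited table.

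Cell cycle genes were split at day 3 and their direction depended on the scaling. Of 56 measured members, 13 rose, 13 fell and 30 did not pass the test as deposited, with 12 higher and 12 lower adjusted over the list alone, whereas the centred counts were 2 higher and 44 lower. The median log2 fold change was 0.00, and the list stood below other genes (cameraPR adjusted p = 0.0139, and 9.68e-10 when centred). MKI67, a marker of proliferating cells, fell by 0.21 ± 0.07 in the authors' deposited table (adjusted p = 0.00315). KIF23, a kinesin of cytokinesis, fell by 0.53 ± 0.09 in the authors' deposited table. UHRF1, which guides maintenance methylation of DNA (chr19:4903080-4962154, plus strand), rose by 1.1 ± 0.08 in the authors' deposited table and remained higher when centred. MCM6, a subunit of the replicative helicase, rose by 0.46 ± 0.09 in the authors' deposited table but had -0.07 when centred (adjusted p = 0.596). Among 14 cell cycle inhibitors and RB family genes, 9 rose as deposited, with 10 higher and 0 lower adjusted over the list alone. Centring gave 3 higher and 3 lower (cameraPR adjusted p = 0.339). CDKN1C, the inhibitor p57, rose by 4.48 ± 0.47 and CDKN1A, the inhibitor p21, by 0.78 ± 0.15 in the authors' deposited table, and the CDKN1A call was lost when centred (adjusted p = 0.202).

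Markers of satellite cells and undifferentiated myoblasts went both ways, with 10 of 17 higher and 4 lower as deposited, 11 higher and 4 lower adjusted over the list alone, and 7 higher and 6 lower when centred (cameraPR adjusted p = 0.297). ID1 and ID2, inhibitors of myogenic bHLH factors, fell, with log2 fold changes of -4.18 ± 0.24 and -3.28 ± 0.14 in the authors' deposited table, whereas NCAM1, a surface protein also made by myotubes, rose by 1.68 ± 0.09.

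Glycolysis and interferon-stimulated genes were lower at day 3. Of 24 measured glycolysis genes, 5 rose, 15 fell and 4 did not pass the test, the same numbers adjusted over the list alone and 4 higher and 17 lower when centred (cameraPR adjusted p = 4.07e-07). LDHA and the pyruvate kinase PKM fell, with log2 fold changes of -1.53 ± 0.08 and -1.11 ± 0.08, while HK2, the hexokinase of muscle, rose by 1.57 ± 0.12 in the authors' deposited table. GAPDH, often used as a reference transcript and named after its values were seen, fell by 0.62 ± 0.08 in the authors' deposited table. Of 23 interferon-stimulated genes, 0 rose, 18 fell and 5 did not pass the test, the same adjusted over the list alone, with 0 higher and 22 lower when centred (cameraPR adjusted p = 8.95e-16). IFI6, MX2 and IFI27, all induced by type I interferon, fell, with log2 fold changes of -1.26 ± 0.08, -1.83 ± 0.12 and -3.72 ± 0.28 in the authors' deposited table. Among 17 inflammatory cytokine genes, 4 rose and 4 fell, the same adjusted over the list alone. When centred, the counts were 1 higher and 6 lower. That list stood below other genes as deposited but not when centred (cameraPR adjusted p = 0.0324 and 0.180). CXCL8, the neutrophil attractant interleukin 8, fell by 4.84 ± 0.61 in the authors' deposited table.

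Markers of other cell types were also measured. Fibroblast and matrix genes gave 10 higher and 13 lower of 28, the same adjusted over the list alone, and 7 higher and 17 lower when centred (cameraPR adjusted p = 0.0138). TNC, the matrix protein tenascin C (chr9:115019578-115118257, minus strand), fell by 4.75 ± 0.08 in the authors' deposited table, while SPARC, a collagen-binding matrix protein, and CCN2, connective tissue growth factor, rose by 1.99 ± 0.07 and 2.21 ± 0.09. Smooth muscle and pericyte genes gave 4 higher and 6 lower of 14, 4 higher and 7 lower adjusted over the list alone, and 3 higher and 7 lower when centred (cameraPR adjusted p = 0.0138). They were led by ACTG2, the enteric smooth muscle actin, which fell by 4.52 ± 0.13 in the authors' deposited table (Wald score -33.9). The actin ACTA2 of the same list went the other way, with a rise of 2.16 ± 0.11 (Wald score 19.1). Adipocyte genes gave 5 higher and 0 lower of 10, the same adjusted over the list alone, and 3 higher and 0 lower when centred (cameraPR adjusted p = 0.999). CEBPB, an early factor of fat cell formation, rose by 1.26 ± 0.14 in the authors' deposited table. Endothelial genes gave 2 higher and 2 lower of 8, unchanged adjusted over the list alone and when centred (cameraPR adjusted p = 0.342). ROBO4, a receptor of vessel endothelium, fell by 2.74 ± 0.35 in the authors' deposited table.

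Genes that package, copy and transcribe mtDNA rose with the general upward movement. TFAM, the protein that coats and compacts mtDNA in nucleoids (chr10:58385022-58399221, plus strand), had a log2 fold change of 0.48 ± 0.16 in the authors' deposited table (adjusted p = 0.00596), and of -0.05 when centred (adjusted p = 0.865). SSBP1, the single-strand binding protein of mtDNA, and LONP1, a matrix protease that degrades TFAM, rose by 0.53 ± 0.13 and 0.50 ± 0.12 in the authors' deposited table, and neither call held when centred (-0.03 for LONP1 and 0.00 for SSBP1). POLG, the catalytic subunit of the mtDNA polymerase (chr15:89305198-89334861, minus strand), rose by 0.93 ± 0.12, the helicase TWNK by 1.31 ± 0.26 and the transcription factor TFB2M by 1.02 ± 0.18 in the authors' deposited table, and these 3 remained higher when centred (adjusted p of 0.00292, 0.0111 and 0.0186). POLG2, the accessory subunit of the polymerase, and POLRMT, the mitochondrial RNA polymerase, rose by 0.88 ± 0.23 and 0.71 ± 0.15 in the authors' deposited table but not when centred (adjusted p of 0.260 and 0.420). ATAD3A, a membrane ATPase near nucleoids, had 0.39 ± 0.18 and did not pass in the authors' deposited table (adjusted p = 0.0545). Of the 41 measured genes of the list, 34 rose, 0 fell and 7 did not pass the test, with 35 higher and 0 lower adjusted over the list alone. Centring gave 8 higher and 5 lower. The list stood above other genes as deposited but not when centred (cameraPR adjusted p = 0.0246 and 0.283). Its 3 members with the smallest adjusted p were MTERF2, a mitochondrial termination factor family member, FASTKD5, which acts in mitochondrial RNA maturation, and LRPPRC, which stabilises mitochondrial mRNAs, with 2.46 ± 0.16, 1.84 ± 0.12 and 1.09 ± 0.07 in the authors' deposited table, and all 3 remained higher when centred.

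The mRNAs encoded in mtDNA itself gave 11 of 11 higher as deposited, the same adjusted over the list alone, and 4 higher and 0 lower when centred, and the list call was lost when centred (cameraPR adjusted p = 0.000133 and 0.453). MT-CO3, MT-CO1 and the merged MT-ATP8-6 entry rose by 0.84 ± 0.06, 0.83 ± 0.06 and 0.80 ± 0.06 in the authors' deposited table. Of the nuclear-encoded respiratory chain genes, those called were all higher as deposited, few were called when centred, and none of the 4 list tests passed. As deposited, 18 of 37 complex I genes, 12 of 13 complex II and III genes, 12 of 13 complex IV genes and 14 of 16 complex V genes rose and 0 fell. Adjusted over the list alone, 15, 12, 12 and 14 rose. When centred, 0, 0, 1 and 0 were higher and 2, 2, 1 and 1 lower (cameraPR adjusted p of 0.954, 0.539, 0.623 and 0.411). Their first members were NDUFS1, UQCRC2, COX5B and ATP5F1A at 0.59 ± 0.09, 0.75 ± 0.10, 0.73 ± 0.10 and 0.61 ± 0.08 in the authors' deposited table, and none of these calls held when centred. Of 78 mitochondrial ribosomal protein genes, 46 were higher and the list did not pass (46 adjusted over the list alone, 4 higher and 3 lower when centred, cameraPR adjusted p = 0.711). Of 84 cytosolic ones, 70 were higher (71 adjusted over the list alone), but 4 higher and 14 lower when centred, and the list's direction turned from above to below other genes (cameraPR adjusted p = 0.00892 and 0.518). MRPS25, a small-subunit protein, rose by 1.60 ± 0.12 and RPS3A by 0.89 ± 0.07 in the authors' deposited table, and both remained higher when centred.

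PPARGC1A, the coactivator PGC-1α that drives mitochondrial biogenesis (chr4:23755041-23904089, minus strand), had the highest fold change of its list, 5.34 ± 0.22 in the authors' deposited table (adjusted p = 1.85e-122). In all, 9 of 15 biogenesis regulators rose (9 adjusted over the list alone), with 3 higher and 0 lower when centred (cameraPR adjusted p = 0.335). Mitochondrial dynamics and cristae genes gave 16 higher of 22 (16 adjusted over the list alone, 3 higher and 1 lower when centred, cameraPR adjusted p = 0.386). The fission factor MFF led this list at 1.28 ± 0.11 in the authors' deposited table. Genes of the TCA cycle and pyruvate dehydrogenase gave 23 higher and 1 lower of 29 (24 higher and 1 lower adjusted over the list alone, 5 higher and 4 lower when centred, cameraPR adjusted p = 0.342). IDH2, the NADP-dependent isocitrate dehydrogenase, led this list at 0.95 ± 0.09 in the authors' deposited table. Fatty acid oxidation genes gave 14 higher and 3 lower of 22, the same adjusted over the list alone, and 4 higher and 5 lower when centred (cameraPR adjusted p = 0.0521). ACSL1, which activates long-chain fatty acids, led this list at 5.10 ± 0.11 in the authors' deposited table. Nucleotide supply genes gave 10 higher and 2 lower of 20, the same adjusted over the list alone, and 3 higher and 8 lower when centred (cameraPR adjusted p = 0.8). SAMHD1, a deoxynucleotide hydrolase, led this list at 0.84 ± 0.08 in the authors' deposited table. Mitophagy genes gave 6 higher and 3 lower of 14, the same adjusted over the list alone, and 4 higher and 5 lower when centred (cameraPR adjusted p = 0.954). The autophagy receptor SQSTM1 led this list at 1.52 ± 0.08 in the authors' deposited table. Stress response genes gave 13 higher and 2 lower of 25, the same adjusted over the list alone, and 5 higher and 8 lower when centred (cameraPR adjusted p = 0.954). HERPUD1, an endoplasmic reticulum protein of that response, led this list at 1.11 ± 0.11 in the authors' deposited table.

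The 6 highest fold changes among called genes with a mean of 100 or more included 5 genes without reads at day 0. Against the level of 3 scaled counts over 2 libraries, ZBTB16, a glucocorticoid-induced transcription factor (chr11:114059593-114250676, plus strand), was at least 1013-fold higher and PTGDS, prostaglandin D synthase, at least 675-fold higher, as computed from the authors' deposited table. The bounds for the transcription factor TFCP2L1, the secreted Wnt antagonist SFRP5 and the myosin chaperone UNC45B were 374, 238 and 212, also computed from the authors' deposited table. PHACTR3, a regulator of protein phosphatase 1, had under 2 scaled counts per library at day 0 and a log2 fold change of 10.54 ± 1.59 in the authors' deposited table. At the other end, MPP4, a membrane scaffold protein (chr2:201644870-201698694, minus strand), and MMP1, the interstitial collagenase, fell, with log2 fold changes of -6.22 ± 0.29 and -5.65 ± 0.29 in the authors' deposited table. WIF1, a secreted Wnt inhibitor, PLEKHG4B, HHIPL2 and COL13A1, a transmembrane collagen, fell, with log2 fold changes of -5.16 ± 0.45, -5.16 ± 0.32, -4.95 ± 0.34 and -4.84 ± 0.46 in the authors' deposited table.

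By the authors' deposited table, 8528 of 15121 genes differed between day 3 and day 0 at an adjusted p under 0.05 (DESeq2 Wald test, Benjamini-Hochberg), 7426 higher and 1102 lower. When centred, 5410 differed, 2519 higher and 2891 lower, so the share of higher genes among those called went from 87.1% to 46.6%, and 207 genes turned from higher to lower. At a change of at least 2-fold the counts were 2340 higher and 547 lower as deposited, against 977 and 1031 when centred. Of the 33 lists, 10 stood above and 6 below other genes as deposited, and 7 above and 5 below when centred. Of these 16 list calls, 7 held under every alternative setting tried (sarcomere, excitation-contraction, acetylcholine receptor, glycolysis, glucocorticoid, interferon and cholesterol genes) and 9 were lost under at least 1. The list test compares members with other genes, and its direction was downward while the median fold change lay above 0 for satellite cell, nucleotide supply, adipocyte, endothelial and, by under 0.01, cell cycle genes. Wald scores grow with precision, so under a general upward shift a list with small SEs can stand above other genes without larger changes. Cytosolic ribosomal protein genes did so at a median of 0.49, against 0.53 for genes with a mean of 100 or more. An inter-gene correlation cannot be estimated without values per library, and calls under larger preset correlations are given with the other settings. Genes with near-identical copies, such as ribosomal protein, myosin heavy chain and mitochondrial genes, may share reads, and how such reads were assigned is not given in the sources used here.

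After 6 days the same muscle programme stood higher still for many genes. In the authors' deposited table for day 6, MYH3 had a log2 fold change of 11.26 ± 0.27 and MYOG of 9.05 ± 0.39 (adjusted p = 3.2e-119), with implied levels of 122618 and 5301 scaled counts per library. CKM, again with under 1 scaled count per library at day 0, had 13.92 ± 1.05 and PAX7 had 3.18 ± 0.99 in the authors' deposited table. MYF5 fell by 2.35 ± 0.28 in the authors' deposited table, and MYOD1, at 0.46 ± 0.25, did not pass (adjusted p = 0.144).

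Of 51 measured sarcomere genes, 45 rose, 0 fell and 6 did not pass the test, with 47 higher and 0 lower adjusted over the list alone. When centred, the counts were 44 higher and 0 lower (median log2 fold change 7.88, or 7.34 with 9 members at their bound, cameraPR adjusted p = 7.37e-107). Besides MYH3, its first members were NEB at 8.40 ± 0.21 and TNNI1, the slow skeletal troponin I, at 11.09 ± 0.31 in the authors' deposited table. Excitation-contraction genes gave 19 higher and 0 lower of 26, 19 higher and 1 lower adjusted over the list alone, and 19 higher and 1 lower when centred (cameraPR adjusted p = 7.65e-22). RYR1, ATP2A1, the calcium pump of fast fibres, and STAC3 rose by 9.30 ± 0.27, 7.84 ± 0.26 and 4.64 ± 0.22 in the authors' deposited table. Acetylcholine receptor and postsynapse genes gave 10 higher and 0 lower of 12, the same adjusted over the list alone, and 9 higher and 0 lower when centred (cameraPR adjusted p = 1.01e-18). CHRND, the delta subunit, had 8.21 ± 0.32 and CHRNG had 5.69 ± 0.31 in the authors' deposited table. Myoblast fusion genes gave 9 higher and 0 lower of 13, the same adjusted over the list alone, and 9 higher and 2 lower when centred (cameraPR adjusted p = 1e-09). MYMK and MYMX, the fusogens myomaker and myomixer, rose by 8.21 ± 0.44 and 5.51 ± 0.32 in the authors' deposited table. Myogenic regulators gave 8 higher and 1 lower of 14, 8 higher and 2 lower adjusted over the list alone, and 6 higher and 2 lower when centred (cameraPR adjusted p = 0.000545). MEF2C, a partner of the myogenic factors, had 4.48 ± 0.24 in the authors' deposited table. Muscle metabolism genes gave 16 higher and 1 lower of 23, 17 higher and 1 lower adjusted over the list alone, and 12 higher and 1 lower when centred (cameraPR adjusted p = 2.43e-10). ENO3, the muscle enolase, had 4.86 ± 0.21 and FABP3, the heart and muscle fatty acid-binding protein, had 7.28 ± 0.32 in the authors' deposited table.

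Cell cycle genes were lower at day 6 in both scalings. Of 56 measured, 13 rose, 31 fell and 12 did not pass the test, with 15 higher and 31 lower adjusted over the list alone. Centring gave 8 higher and 32 lower (median log2 fold change -0.88, cameraPR adjusted p = 2.35e-08). MKI67 fell by 1.38 ± 0.22 in the authors' deposited table (adjusted p = 1.3e-08), and UHRF1 rose by 2.05 ± 0.22. The spindle genes DLGAP5 and NUF2 fell, with -1.96 ± 0.21 and -1.85 ± 0.22 in the authors' deposited table. Cell cycle inhibitors and RB family genes gave 7 higher and 1 lower of 14, the same adjusted over the list alone, and 6 higher and 2 lower when centred (cameraPR adjusted p = 0.0139). CDKN1C had 6.92 ± 0.41 and CDKN1A had 2.08 ± 0.24 in the authors' deposited table. Satellite cell and undifferentiated myoblast markers gave 9 higher and 5 lower of 18, unchanged adjusted over the list alone and when centred (cameraPR adjusted p = 0.954). ID1 and ID2 fell, with log2 fold changes of -6.52 ± 0.47 and -4.07 ± 0.25 in the authors' deposited table, and NCAM1 rose by 3.63 ± 0.22.

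The glucocorticoid and cholesterol lists remained higher. Of 23 glucocorticoid response genes, 14 rose, 3 fell and 6 did not pass the test, the same adjusted over the list alone, with 11 higher and 4 lower when centred (median log2 fold change 2.03, cameraPR adjusted p = 1.32e-06). FKBP5, TSC22D3 and FOXO1, a transcription factor of fasting and atrophy, had 4.45 ± 0.21, 5.60 ± 0.24 and 4.40 ± 0.29 in the authors' deposited table. Each of the 23 measured cholesterol synthesis genes rose as deposited and adjusted over the list alone, 22 were higher when centred, and the median log2 fold change was 3.45 (cameraPR adjusted p = 2.51e-60). HMGCS1 and MSMO1, a sterol oxidase, rose by 4.78 ± 0.21 and 4.33 ± 0.23 in the authors' deposited table.

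Glycolysis genes again fell more often than they rose, with 6 higher and 12 lower of 24, the same adjusted over the list alone, and 2 higher and 14 lower when centred (cameraPR adjusted p = 0.0270). The isozymes parted, since ENO3 rose as above while ENO2, the neuronal enolase, and LDHA fell, with log2 fold changes of -1.62 ± 0.23 and -1.82 ± 0.22 in the authors' deposited table. Interferon-stimulated genes gave 3 higher and 9 lower of 23, the same adjusted over the list alone, and 0 higher and 12 lower when centred (cameraPR adjusted p = 0.00320). IFI27, OASL and MX2 fell, with log2 fold changes of -1.89 ± 0.33, -1.71 ± 0.32 and -1.52 ± 0.29 in the authors' deposited table. Inflammatory cytokine genes gave 2 higher and 3 lower of 17, the same adjusted over the list alone, and 1 higher and 4 lower when centred (cameraPR adjusted p = 0.0455, and 0.108 when centred). CXCL8 had -4.39 ± 0.62 in the authors' deposited table.

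Fibroblast and matrix genes gave 7 higher and 8 lower of 28, the same adjusted over the list alone, and 5 higher and 9 lower when centred (cameraPR adjusted p = 0.0270, downward although the median was 0.05). TNC and MMP2, a gelatinase of the matrix, fell, with log2 fold changes of -4.67 ± 0.23 and -2.44 ± 0.23 and SPARC rose by 2.37 ± 0.21 in the authors' deposited table. Smooth muscle and pericyte genes gave 5 higher and 3 lower of 14, 6 higher and 3 lower adjusted over the list alone, and 3 higher and 4 lower when centred (cameraPR adjusted p = 0.924). ACTA2, the vascular smooth muscle actin also made by young myotubes, had 4.70 ± 0.21 in the authors' deposited table. Adipocyte genes gave 5 higher and 0 lower of 10, the same adjusted over the list alone, and 4 higher and 0 lower when centred (cameraPR adjusted p = 0.0856, and 0.0378 when centred). CD36, a fatty acid transporter that is also on the oxidation list, had 6.24 ± 0.38 in the authors' deposited table. Endothelial genes gave 1 higher and 1 lower of 8, 1 higher and 2 lower adjusted over the list alone, and 1 higher and 2 lower when centred (cameraPR adjusted p = 0.736). CLDN5, a tight-junction protein, had 6.47 ± 0.99 in the authors' deposited table.

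TFAM did not pass at day 6, with 0.44 ± 0.26 in the authors' deposited table (adjusted p = 0.184). POLG2, SSBP1, TFB2M and ATAD3A, at 0.11 ± 0.35, 0.52 ± 0.24, 0.48 ± 0.28 and 0.65 ± 0.29, did not pass either in the authors' deposited table (adjusted p of 0.850, 0.0797, 0.181 and 0.0656). POLG, TWNK, POLRMT and LONP1 rose by 0.94 ± 0.24, 1.03 ± 0.35, 0.73 ± 0.27 and 0.68 ± 0.25 in the authors' deposited table, and none of these 4 calls held when centred (adjusted p of 0.0548, 0.146, 0.331 and 0.361). For POLG and TWNK the SEs were wider than at day 3 (0.12 and 0.26). Day 6 minus day 3, they differed by 0.01 and -0.27 as deposited and by 0.20 and -0.08 when centred. TFB2M differed by -0.54, and by -0.35 when centred, and none of these 3 genes passed the difference test in either scaling. Of the 41 genes of mtDNA packaging, replication and transcription, 19 rose, 0 fell and 22 did not pass the test, with 22 higher and 0 lower adjusted over the list alone. When centred, the counts were 7 higher and 1 lower (cameraPR adjusted p = 0.0583). MTERF2, FASTKD5 and HSD17B10, a subunit of mitochondrial RNase P, rose by 1.90 ± 0.27, 1.49 ± 0.24 and 1.72 ± 0.29 in the authors' deposited table, and these calls held when centred. PPARGC1A rose by 5.92 ± 0.29 in the authors' deposited table (adjusted p = 4.89e-91), within 5 of 15 biogenesis regulators that rose (5 adjusted over the list alone, 2 higher and 0 lower when centred, cameraPR adjusted p = 0.126).

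Of the mRNAs encoded in mtDNA, 10 of 11 rose (11 adjusted over the list alone), 6 were higher when centred, and the list stood above other genes in both scalings (cameraPR adjusted p = 0.00635 and 0.0378). However, that list call did not hold under every alternative setting tried. MT-ND6, MT-ND1 and MT-CO1 rose by 1.16 ± 0.20, 1.1 ± 0.21 and 1.09 ± 0.20 in the authors' deposited table. As deposited, 9 of 37 complex I, 6 of 13 complex II and III, 10 of 14 complex IV and 8 of 16 complex V genes rose and 0 fell. The counts were 9, 7, 11 and 9 adjusted over the list alone, and 2, 1, 3 and 0 when centred, with 1 complex V gene then lower (cameraPR adjusted p of 0.340, 0.245, 0.0599 and 0.297). COX6A2, the muscle form of a complex IV subunit, stood apart at 7.03 ± 0.75, beside NDUFB9 at 1.51 ± 0.30, CYC1 at 1.05 ± 0.26 and ATP5F1C at 0.78 ± 0.21 in the authors' deposited table, and the ATP5F1C call was lost when centred. Mitochondrial ribosomal protein genes gave 19 higher of 78 (10 adjusted over the list alone, 3 higher and 0 lower when centred, cameraPR adjusted p = 0.340). MRPS25 led this list at 1.18 ± 0.24 in the authors' deposited table. Cytosolic ones gave 30 of 84 (30 adjusted over the list alone, 4 higher and 1 lower when centred, cameraPR adjusted p = 0.122). RPS3A led this list at 0.92 ± 0.20 in the authors' deposited table.

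Genes of the TCA cycle and pyruvate dehydrogenase gave 15 higher and 1 lower of 29 (18 higher and 1 lower adjusted over the list alone, 6 higher and 2 lower when centred, cameraPR adjusted p = 0.1). IDH2 led this list at 1.93 ± 0.20 in the authors' deposited table. Fatty acid oxidation genes gave 10 higher and 3 lower of 22 (11 higher and 3 lower adjusted over the list alone, 6 higher and 3 lower when centred, cameraPR adjusted p = 0.00104). Mitochondrial dynamics and cristae genes gave 8 higher and 1 lower of 22 (9 higher and 1 lower adjusted over the list alone, 2 higher and 1 lower when centred, cameraPR adjusted p = 0.411). OMA1, a protease that cleaves OPA1, led this list at 1.17 ± 0.25 in the authors' deposited table. Mitophagy genes gave 4 higher and 2 lower of 14 (6 higher and 3 lower adjusted over the list alone, 3 higher and 3 lower when centred, cameraPR adjusted p = 0.886). BNIP3, a hypoxia-induced mitophagy receptor, fell by 1.63 ± 0.20 in the authors' deposited table. Nucleotide supply genes gave 6 higher and 2 lower of 20, the same adjusted over the list alone, and 3 higher and 4 lower when centred (cameraPR adjusted p = 0.954). ABAT, a transaminase linked to mitochondrial nucleoside metabolism, led this list at 5.41 ± 0.58 in the authors' deposited table. Stress response genes gave 16 higher and 0 lower of 25 (17 higher and 1 lower adjusted over the list alone, 10 higher and 2 lower when centred), and the list call was lost when centred (cameraPR adjusted p = 0.0185 and 0.0542). TRIB3, a pseudokinase induced by stress, had 2.54 ± 0.40 in the authors' deposited table.

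**Figure D2:**
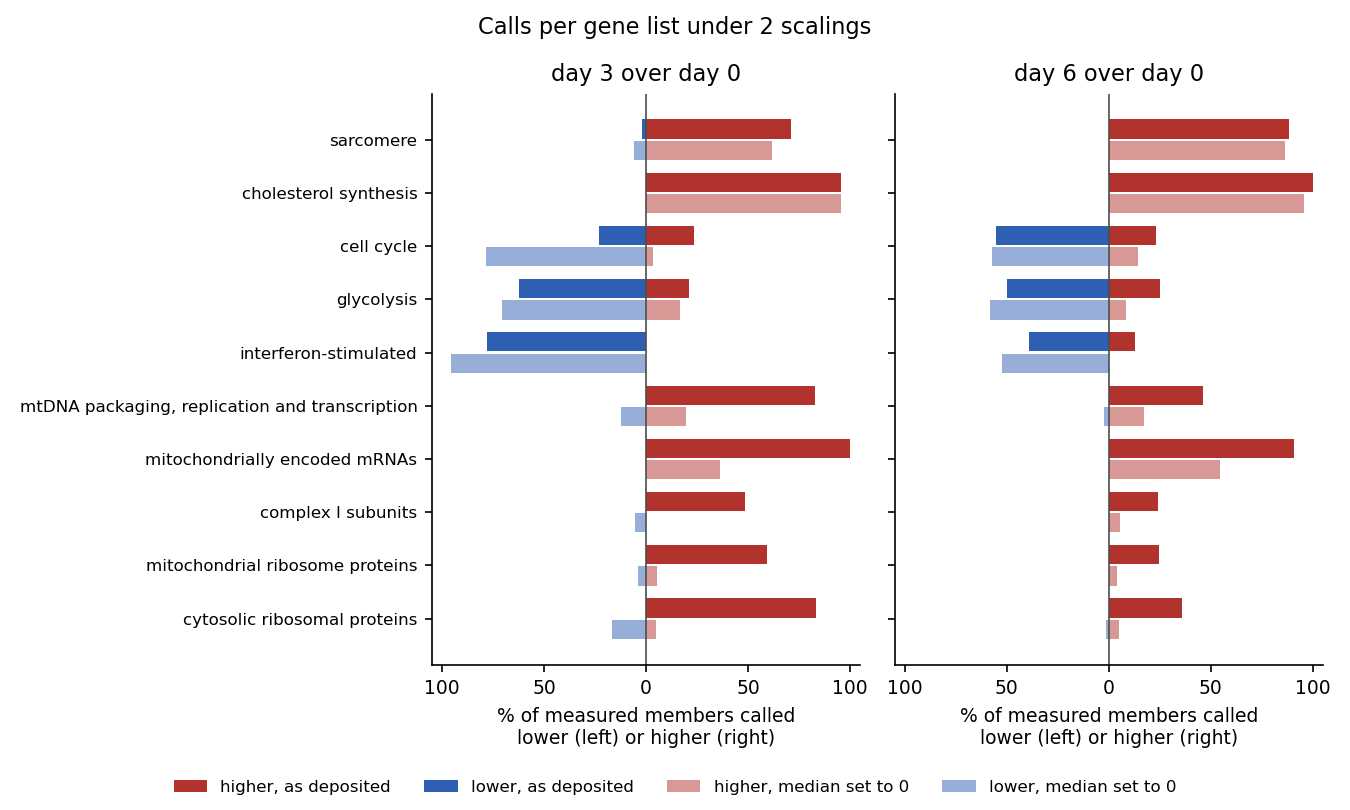
Share of measured members of 10 gene lists called higher (right, red) or lower (left, blue) at an adjusted p under 0.05, as deposited (dark) and with the median set to 0 (light), for day 3 and day 6 over day 0. Most sarcomere and cholesterol synthesis genes were called higher in both scalings, whereas cytosolic ribosomal protein genes went from 70 of 84 called higher to 4 higher and 14 lower at day 3.

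The 6 highest fold changes at day 6 were again led by genes without reads at day 0. As computed from the authors' deposited table, UNC45B (chr17:35147817-35189345, plus strand) was at least 4423-fold higher, CASQ2, the calcium-binding protein calsequestrin, at least 3887-fold, CACNA1S, the voltage sensor of excitation-contraction coupling, at least 2238-fold and PTGDS at least 1225-fold. MYH8, the perinatal myosin heavy chain, had 13.67 ± 0.86 in the authors' deposited table, from an implied 1.44 scaled counts per library at day 0, and CKM completed the set. MMP1 had -10.08 ± 1.37 in the authors' deposited table, with under 1 scaled count per library left at day 6. ID1, MPP4, WIF1, PLEKHG4B and DOCK2, a Rac activator, fell, with log2 fold changes of -6.52 ± 0.47, -6.48 ± 0.36, -5.71 ± 0.57, -5.71 ± 0.41 and -5.64 ± 0.47 in the authors' deposited table.

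By the authors' deposited table, 4806 of 14938 genes differed between day 6 and day 0 (DESeq2 Wald test, Benjamini-Hochberg adjusted p under 0.05), 3577 higher and 1229 lower. When centred, 3774 differed, 1865 higher and 1909 lower, and the share of higher genes went from 74.4% to 49.4%. At a change of at least 2-fold the counts were 2022 higher and 854 lower as deposited, against 1327 and 1299 when centred. Of the 33 lists, 12 stood above and 5 below other genes as deposited, and 12 above and 4 below when centred. Of these 17 list calls, 9 held under every alternative setting tried (myogenic regulators, fusion, sarcomere, excitation-contraction, acetylcholine receptor, muscle metabolism, cell cycle, glucocorticoid and cholesterol genes) and 8 were lost under at least 1. The direction of the list test was downward while the median fold change lay above 0 for fibroblast and matrix, satellite cell, nucleotide supply, mitophagy, smooth muscle and endothelial genes, and of these only the fibroblast and matrix test passed.

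**Figure D3:**
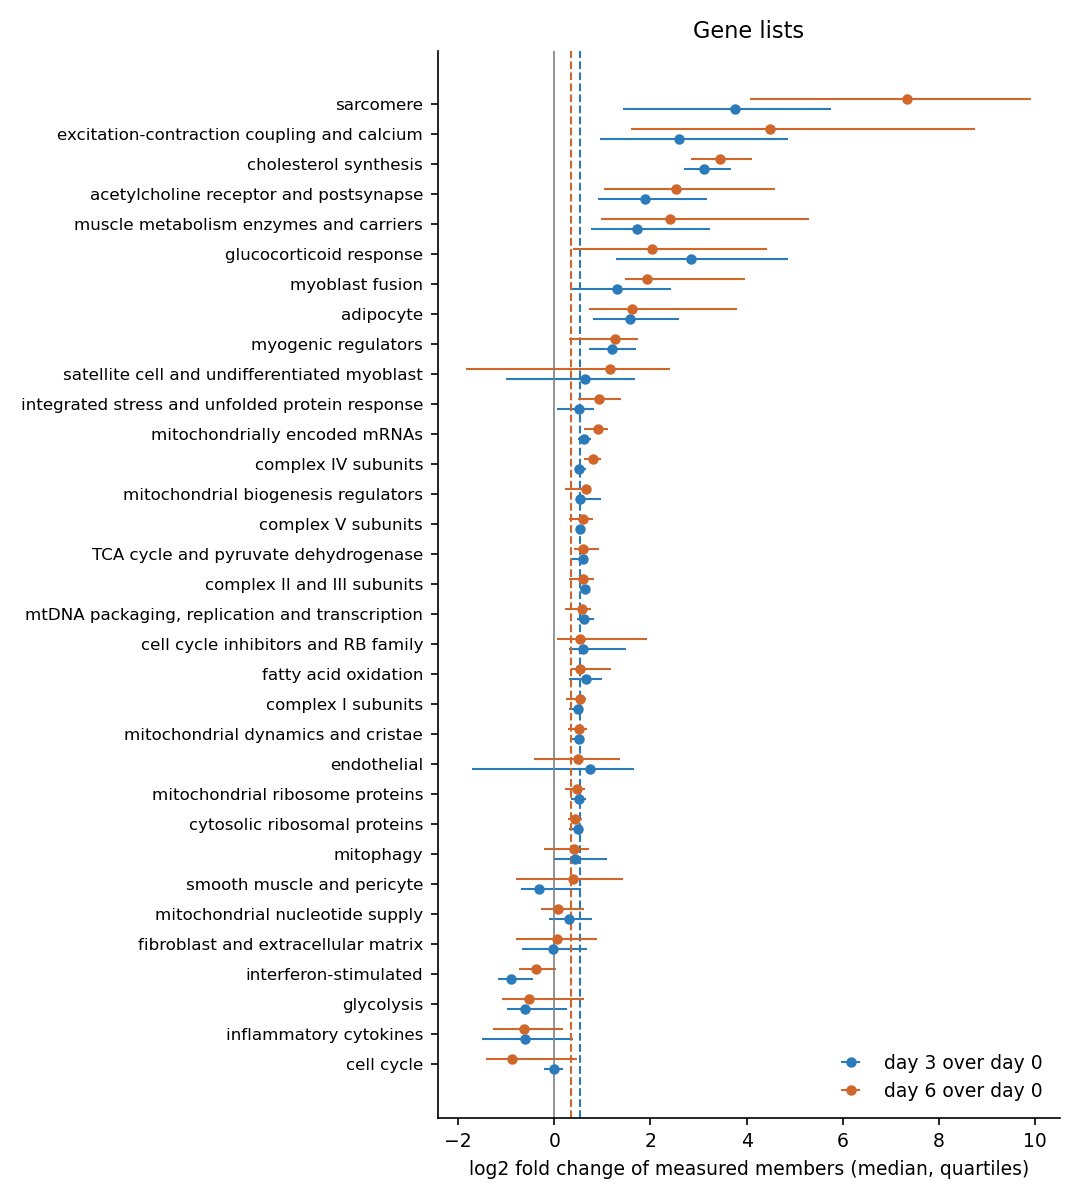
Median log2 fold change (point) and quartiles (bar) of the measured members of each of the 33 gene lists, day 3 over day 0 in blue and day 6 over day 0 in orange, with members that had a group without reads placed at their bound. The sarcomere medians of 3.76 and 7.34 lie far to the right of the dashed lines, which mark the medians of all genes with a mean of 100 or more (0.53 and 0.34). The medians of the respiratory chain complex lists lie between 0.49 and 0.64 at day 3. At day 6 they lie between 0.53 and 0.80, to the right of the day 6 line and furthest from it for complex IV.

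**Figure D4:**
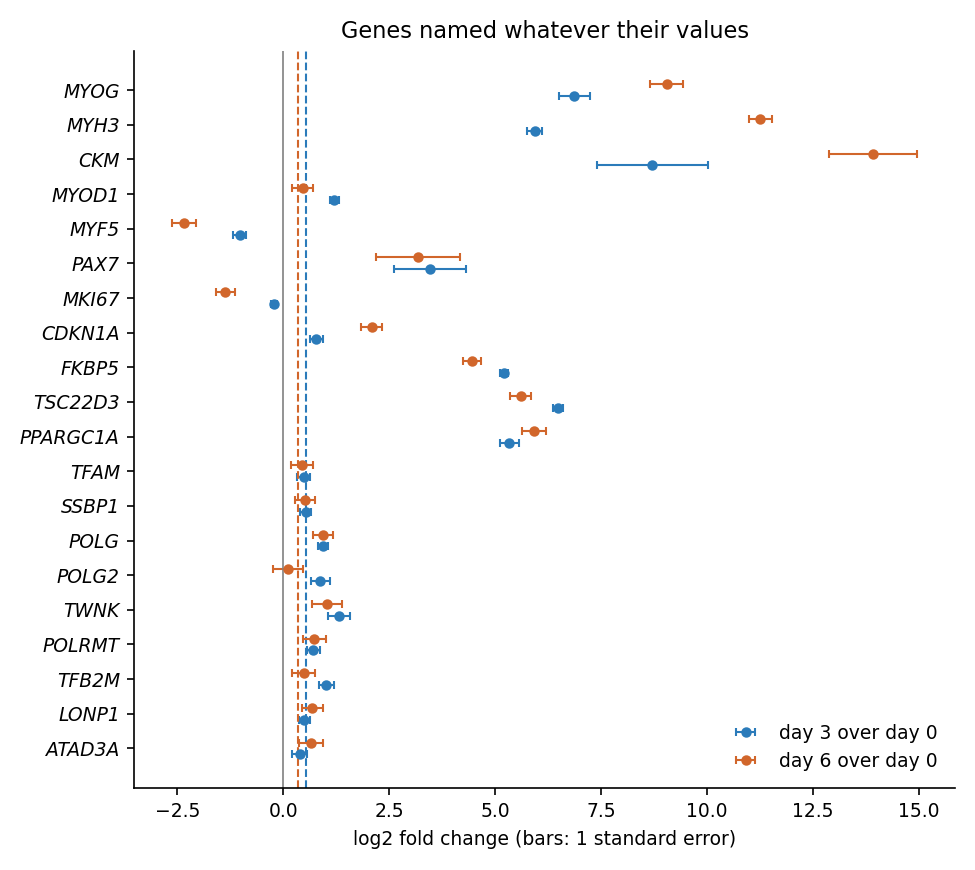
Log2 fold change with 1 SE of the 20 genes named whatever their values, day 3 over day 0 in blue and day 6 over day 0 in orange. MYOG, MYH3 and CKM lie at 6.87 or more except MYH3 at day 3 (5.93), whereas TFAM lies at 0.48 and 0.44, next to the dashed lines at the medians of all genes with a mean of 100 or more.

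Day 6 and day 3 were then compared with each other through their common day 0. Of the 6 highest differences among called genes with a mean of 100 or more, 5 were those of sarcomere genes. By a two-sided z test, run here on the difference of the log2 fold changes in the authors' deposited table for each day, ACTA1, the skeletal muscle actin, was higher at day 6 by 5.78 ± 0.55, MYH3 by 5.33 ± 0.32, CKM by 5.21 ± 1.68, MYL4, an embryonic myosin light chain, by 5.0 ± 0.45, MYOZ2, a Z-disc protein, by 4.70 ± 0.54 and MYH8 by 4.59 ± 1.22. The 6 lowest differences by the same rule, again computed from the authors' deposited table for each day, were those of MMP1 at -4.43 ± 1.40, the cadherin CDH6 at -3.88 ± 0.45, the carboxypeptidase CPA4 at -3.05 ± 0.36, DOCK2 at -2.44 ± 0.53, TSPOAP1 at -2.38 ± 0.58 and the efflux transporter ABCC3 at -2.37 ± 0.38. Among genes named in advance, MYOG rose further by 2.18 ± 0.53 while MYF5 (-1.32 ± 0.32), MKI67 (-1.16 ± 0.23), FKBP5 (-0.76 ± 0.23) and TSC22D3 (-0.88 ± 0.27) were lower at day 6 than at day 3, as computed here from the authors' deposited table for each day. Of these, the FKBP5 and TSC22D3 calls were lost when centred, with differences of -0.57 and -0.69 (adjusted p of 0.188 and 0.145). The difference for TFAM, computed here from the authors' deposited table for each day, was -0.04 ± 0.30 and did not pass (adjusted p = 1.0), nor did that for PPARGC1A (0.58 ± 0.37, adjusted p = 0.569).

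Sarcomere genes gave 28 higher and 0 lower at day 6 than at day 3 of 53 compared, and 29 higher and 0 lower when centred (median difference 3.37, cameraPR adjusted p = 4.71e-88). Excitation-contraction genes gave 10 higher and 0 lower of 25 in both scalings (median 1.86, adjusted p = 3.68e-16). Members of these lists without reads at day 0, such as UNC45B (4.33 ± 5.66), had SEs too wide for a call. The counts of higher genes may therefore be too low. Cell cycle genes gave 2 higher and 29 lower of 56, and 7 higher and 24 lower when centred (median -0.83, adjusted p = 6.89e-12), and glucocorticoid response genes 0 higher and 5 lower of 24, and 0 higher and 2 lower when centred (median -0.81, adjusted p = 0.00021). Interferon-stimulated genes gave 4 higher and 0 lower of 23, and 6 higher and 0 lower when centred (median 0.53, adjusted p = 1.13e-08). No single mRNA of mtDNA passed as deposited, and 1 was higher when centred, but the 11 together stood above other genes (median 0.20, adjusted p = 0.00499). That test took the preset inter-gene correlation of 0.01, and a stronger correlation among these mRNAs would make its p too small. The mtDNA packaging list did not pass in either scaling (median -0.10, and 0.09 when centred, adjusted p of 0.817 and 0.405). The list calls of this paragraph held when centred, with the same directions.

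In all, 948 of 16473 genes differed between the days, 376 higher and 572 lower at day 6 (Benjamini-Hochberg adjusted p under 0.05). The split turned when centred, to 513 higher and 317 lower. The test left out the covariance that the shared day 0 libraries bring, which makes it conservative. In genes without reads at day 0, the day 0 term fills most of the SE, and such genes could hardly be called. By this z test CASQ2 had a difference of 5.52 ± 5.66 (adjusted p = 0.876) and CACNA1S one of 4.31 ± 5.66 (adjusted p = 0.959). Fold changes of day 3 and day 6 correlated across 10618 genes with a mean of 100 or more in both tables (Pearson 0.876, Spearman 0.769), where unchanged groups sharing the day 0 libraries gave 0.340 and 0.288 in 100 simulated draws. Genes are not independent replicates and no p is given. The covariance was 0.921 against 0.0213 simulated. Both comparisons called 3117 genes higher (1783 for independent lists) and 784 lower (91.8 for independent lists), and 58 in opposite directions. When centred, 1254 were higher in both (314 for independent lists), 1613 lower in both (374 for independent lists) and 62 opposite. Lists of the same lengths, taken from the ends of simulated unchanged groups that shared the day 0 libraries, had 2380 higher and 230 lower genes in common, and 611 and 700 at the centred lengths (means of 100 draws). The 2 day 0 libraries could not be split, and part of the excess may come from their being shared.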

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

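Of the tests below, those on the median fold change, on counting noise, on the day 0 spread and on an introduced TERT sequence were chosen only after the result was seen. Those on uneven differentiation and on the TERT locus were written before their values were computed. The results below were picked out because day 6 and day 3 differed in their change from day 0 by the test of the difference itself. Values are log2, day 6 minus day 3, and gene differences and their tests were computed here from the authors' deposited table for each day.

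By list median, day 6 stood above day 3 for myoblast fusion (0.82), sarcomere (3.37), excitation-contraction (1.86), acetylcholine receptor (0.76) and muscle metabolism genes (1.88), and for mRNAs of mtDNA (0.20), complex IV (0.19), smooth muscle (0.25), interferon-stimulated (0.53), cholesterol synthesis (0.34) and stress response genes (0.42). It stood below for cell cycle (-0.83) and glucocorticoid response genes (-0.81). For glycolysis genes the test was upward while the median was -0.0384. In 10 lists that did not pass, among them mtDNA packaging and both ribosomal protein lists, the test was also upward with a median under 0.

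Contractile and coupling genes were higher at day 6, computed from the authors' deposited table: ACTA1 (5.78), MYH3 (5.33), MYL4 (5.0), MYOZ2 (4.70), MYH8 (4.59), NEB (3.83), TNNI1 (3.59), TNNT2 (1.1), ACTA2 (2.54), ATP2A1 (2.99), RYR1 (1.62), STAC3 (1.05) and BIN1 (1.58). So were regulators, fusion, receptor and surface genes, MYOG (2.18), MEF2C (2.53), MYMK (3.68), CHRND (2.50), NCAM1 (1.94) and COL13A1 (3.57), computed from the authors' deposited table. Enzymes and carriers higher at day 6 were CKM (5.21), ENO3 (3.21), FABP3 (2.47), CD36 (3.50) and IDH2 (0.97), computed from the authors' deposited table. Cell cycle inhibitors and others higher at day 6 were CDKN1A (1.30), CDKN1C (2.44), UHRF1 (0.95), TRIB3 (1.85), IFI27 (1.83) and IFI6 (1.35), computed from the authors' deposited table.

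Lower at day 6 than at day 3 were the proliferation genes MKI67 (-1.16), DLGAP5 (-1.67), NUF2 (-1.59) and KIF23 (-0.94) and the glucocorticoid-induced genes FKBP5 (-0.76) and TSC22D3 (-0.88), computed from the authors' deposited table. Matrix and surface genes lower at day 6 were MMP1 (-4.43), MMP2 (-1.60), CCN2 (-2.16), CDH6 (-3.88) and CPA4 (-3.05), computed from the authors' deposited table. Others lower at day 6 were MYF5 (-1.32), ID1 (-2.34), MUSK (-0.73), PHKA1 (-1.13), HK2 (-0.86), DOCK2 (-2.44), TSPOAP1 (-2.38), ABCC3 (-2.37) and ACTB (-0.82), computed from the authors' deposited table, of which ACTB was chosen after its values were seen. When centred, the calls of FKBP5, TSC22D3, MUSK, HK2 and ACTB were lost (differences of -0.57, -0.69, -0.54, -0.68 and -0.63), computed from the authors' deposited table. FDFT1, HMGCS1, MCM6, MT-ND6 and NDUFB9 were called higher at day 6 only when centred, computed from the authors' deposited table. CCN2 went from 2.21 at day 3 to 0.06 at day 6 and ABCC3 from 0.67, a call lost when centred, to -1.70 against day 0, in the authors' deposited table.

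The first pattern weighed was the median log2 fold change above 0 on both days. Median-of-ratios scaling over the listed genes was excluded, since such factors, taken from the implied group levels, would leave a median of at most 0.0199, against 0.340 or more in the tables. Scaling to equal totals over the listed genes was excluded by a log2 ratio of implied totals of 0.443 or more. A reference outside the listed genes, such as size factors taken over further features, was left open, because the medians of 10 groups of genes by level differed by at most 0.153. A rise of mRNA per cell relative to other RNA, as a biological account, may give the same even shift and was not tested.

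The second pattern was the larger SEs at day 6. Counting noise was excluded, since genes with a mean of 10000 or more had SEs 3.00 times those of day 3. Spread between the day 0 libraries, which both tables share, was excluded by an implied dispersion 9.31 times that of day 3. Uneven differentiation of the day 6 libraries was left open, because the dispersion of 40 muscle list genes was 1.04 times that of matched random lists (percentile 93.7). These were sarcomere and excitation-contraction genes above a minimum day 0 level. Genes switched on from almost no reads, such as UNC45B and CASQ2, were thus not covered. A technical difference between the day 6 libraries may also be the source and was not tested.

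The third pattern was the level of TERT, the catalytic subunit of telomerase (chr5:1253147-1295069, minus strand), chosen after its values were seen. In the authors' deposited table it fell by 1.12 ± 0.07 at day 3 and by 0.69 ± 0.25 at day 6, and its implied day 0 level of 83552 scaled counts per library ranked 6 of 16719 genes with reads (percentile 99.96). An introduced TERT sequence may give such a level, but this was left open because the neighbouring gene CLPTM1L lay at percentile 90.5, just above the limit set for it. Its implied day 0 level was 2290 scaled counts per library, far below that of TERT. Copy gain or read-through of the whole locus was left open by the same value under the rule written beforehand. However, the other neighbour, SLC6A18, lay at percentile 1.26 with an implied 0.15 scaled counts per library. With neither neighbour near the level of TERT, these values argue against read-through of the whole locus. They cannot settle copy gain, since a silent gene may gain copies without RNA. Whether the cells carried an introduced sequence is not given in the sources used here.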

How the results depend on the processing

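The centred list tests, the centred 2-fold counts and the centring of genes named after their values were seen were chosen only after the data were seen, and the other settings were planned. Comparison tables without values per library limited this part, and leaving out each replicate, a replicate block and refits with a count model or other size factors were not run. No paired analysis was possible because the tables hold no values per library. What depth limited was not tested, and of 16719 and 16882 genes with reads at day 3 and day 6 only the 15121 and 14938 with an adjusted p entered the calls.

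Changed genes at day 3 numbered 2887 with a 2-fold minimum, 5410 when centred and 2008 with both. Higher genes numbered 2340, 2519 and 977, and lower genes 547 with the minimum and 2891 when centred. At day 6, changed genes numbered 2876 with the minimum and 2626 with both, higher genes 2022, 1865 when centred and 1327 with both, and lower genes 1909 when centred. The 2-fold counts fell by construction, and the centred ones moved because the median moved. Adjusted p under 0.01 gave 7197 and 3429 changed genes and 0.1 gave 9268 and 5796, within 1.5 times the reported counts, as did the filters on level. With the covariance for shared day 0 libraries 1425 genes differed between the days, 882 of them lower at day 6, by construction of a smaller variance, and 317 were lower when centred.

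Lists that stood apart at day 3 numbered 9 at a preset correlation of 0.05 and 8 at 0.1, and at day 6 they numbered 9 at 0.1 and 11 with log2 fold changes in place of Wald scores. Of 66 list results, 54 kept their side of the threshold at 0.05, 50 at 0.1, 51 with ranks, 49 with log2 fold changes and 59 when centred. The direction of cytosolic ribosomal protein genes at day 3 reversed with log2 fold changes (adjusted p = 0.982) and when centred (0.518). Their median of 0.49 lay below the 0.53 of genes with a mean of 100 or more. Their place above other genes as deposited thus came from the Wald scores and not from larger changes. The direction of adipocyte genes at day 3 reversed with log2 fold changes (0.0216), but as deposited they hardly had one. Their mean Wald score differed from that of other genes by -0.0011 (cameraPR adjusted p = 0.999), while their median log2 fold change was 1.57. Why their Wald scores did not stand apart was not tested. When centred, 6 lists without a call in either scaling also turned: complex I, complex V, mitophagy, stress response and adipocyte genes at day 3 and endothelial genes at day 6. Of the named gene results, 156 kept their call when centred, 13 lost it and 9 had none in either scaling, of which 3 changed sign. Another 5, all at day 3 and computed from the authors' deposited table, were called and reversed in sign by construction of the shift. ACTB (-0.30) was then called lower, while LONP1 (-0.0344), MCM6 (-0.0714), SSBP1 (-0.000303) and TFAM (-0.0490) had no call left. The correlation of both days was 0.879 at a mean of 10 or more and 0.876 at 1000 or more.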

Other observations

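The 23 gene families of this part were chosen only after the data were seen, and p-values were adjusted over their 46 tests, of which 10 passed as deposited. Replication-dependent histone genes, which are made mainly in S phase, were lower by day 6, when 1 rose and 43 fell of 62 measured as deposited, and 0 rose and 47 fell when centred (median log2 fold change -1.22, cameraPR adjusted p = 1.62e-13). At day 3, 9 rose and 1 fell of 63 measured as deposited, and 1 rose and 33 fell when centred (adjusted p = 0.0823, and 0.0216 when centred), so that their direction depended on the scaling. Of the kinesins, motor proteins many of which act in mitosis, 6 rose and 12 fell of 36 measured as deposited, and 5 rose and 14 fell when centred at day 6 (adjusted p = 0.00940), and the family did not pass at day 3 (11 rose and 4 fell of 35 as deposited, 1 and 17 when centred, adjusted p = 0.333 and 0.0511). Of the cytosolic tRNA synthetases, 16 rose and 0 fell of 20 measured as deposited, and 7 rose and 0 fell when centred at day 6 (adjusted p = 0.0193, and 0.105 when centred). At day 3, 16 of them rose and 0 fell, and the family did not pass (adjusted p = 0.128).

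Annexins and S100 proteins, calcium-binding proteins of membranes, were lower at day 3, when 4 rose and 11 fell of 20 measured as deposited, and 0 rose and 15 fell when centred (adjusted p = 0.000283). At day 6, 3 rose and 7 fell of 20 measured as deposited, and 0 rose and 8 fell when centred (adjusted p = 0.0103). ANXA1, an anti-inflammatory annexin, had log2 fold changes of -1.52 ± 0.08 at day 3 and -2.14 ± 0.21 at day 6 in the authors' deposited table. Of the semaphorins, which guide axons and vessels, 3 rose and 7 fell of 19 measured as deposited, and 3 rose and 9 fell when centred at day 3 (adjusted p = 0.000956). At day 6 the semaphorins did not pass, with 5 higher and 6 lower (adjusted p = 0.127, and 0.17 when centred). SEMA7A and SEMA3A had -3.74 ± 0.15 and -3.32 ± 0.18 at day 3 in the authors' deposited table. Of the matrix metalloproteinases, 3 rose and 6 fell of 16 measured as deposited, and 2 rose and 7 fell when centred at day 3 (adjusted p = 0.00143). At day 6 that family did not pass, with 4 higher and 7 lower of 16 (adjusted p = 0.127, and 0.288 when centred). Wnt ligands and secreted Wnt antagonists passed at day 3 only as deposited, when 4 rose and 6 fell of 21 measured as deposited, and 4 rose and 8 fell when centred (adjusted p = 0.0203, and 0.196 when centred). At day 6 the counts of that family were 7 higher and 9 lower of 22 in both scalings (adjusted p = 0.0532, and 0.145 when centred). Of the HLA genes, which present antigens, 0 rose and 9 fell of 18 measured as deposited, and 0 rose and 13 fell when centred at day 3 (adjusted p = 0.000577). At day 6, 0 rose and 10 fell of 17 measured as deposited, and 0 rose and 11 fell when centred (adjusted p = 0.000283). Integrins, IGF-binding proteins and tubulins passed at day 3 only when centred, below other genes (adjusted p of 0.0476, 0.00932 and 0.0361, and 0.241, 0.0532 and 0.251 as deposited). Of the integrins 8 rose and 8 fell of 25 measured as deposited, and 4 rose and 10 fell when centred. Of the IGF-binding proteins 4 rose and 2 fell of 7 measured as deposited, and 1 rose and 3 fell when centred, and of the tubulins 8 rose and 6 fell of 20 measured as deposited, and 4 rose and 11 fell when centred.

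Some abundant genes had wide errors at day 6, and these were chosen after their values were seen. Of 4085 genes with a mean of 1000 or more, 13 had an implied dispersion above 0.1 at day 6, against 2 of 4234 at day 3. Among them were TTN, with 9.80 ± 1.81, and FN1, the matrix protein fibronectin, with 1.20 ± 0.87 (adjusted p = 0.304) in the authors' deposited table. These 2 genes held 4.40% and 1.53% of the implied total at day 6. Among genes often used as references, ACTB, a cytoplasmic actin, had 0.23 at day 3 and -0.60 at day 6 in the authors' deposited table. Its day 3 call turned from higher to lower when centred (-0.30, adjusted p = 1.36e-05). GAPDH had -0.62 and -0.58 in the authors' deposited table, and was lower in both scalings.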
